A study of Mus musculus with 3 samples.

How the data were processed

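The series holds 3 two-colour arrays of mouse kidney, 1 per nephritic mouse, in 1 group. Per the labels, total RNA of a BALB/c mouse injected with anti-GBM antibody 3 days before was labelled with Cy5 and a control RNA pooled from 5 normal BALB/c mice with Cy3, with the same dyes on every array. The mouse numbers in the labels name separate animals. How the arrays were scanned, background-corrected and normalized is not given in the sources used here.

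The authors deposited 1 table with a log ratio per probe and array, for 16281 probes, and its 3 columns were matched to the samples by their names. The values run from -3.66 to 2.55 and lie around 0: the medians over rows measured on all arrays are 0.019, 0.011 and 0.0012 for replicates 1, 2 and 3. Neither the log base nor the direction is stated, so values were kept on the deposited scale, folds are given on a base-2 reading, and a positive value was taken as nephritic over control, from the dyes in the labels. Under a natural or base-10 logarithm each fold is larger. Exact zeros fill 32.7%, 31.9% and 27.3% of the columns, whereas no other value occurs more than 2 times in a column. They were read as placeholders for a ratio that was not measured, after the data were examined, and a row entered the tests only with a value other than 0 on all 3 arrays. The zeros were not spread evenly: they made up 59.3% of the values of 68 ribosomal protein probes, 39.7% of 73 olfactory receptor probes and 28.3% of all probes with a single symbol, so a gene at 0 is said only to be listed at 0.

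Gene symbols came from the platform annotation of 2016, with gene identifiers compared with a RefSeq gene table of assembly GRCm38.p6. A single symbol was given for 13738 probes, several for 52 and none for 2491; 13694 of the 13738 identifiers were found in the table and 0 symbols changed. The symbols cover 10698 genes. Genes fixed for naming whose symbol alone was given for no probe, such as Havcr1, Spp1 and Icam1, were not analysed here. No coordinates are given because no genome build is named in the sources. Probes of 1 symbol were averaged (limma avereps) and unnamed probes kept as rows of their own. Of 1144 named genes with several measured probes, 407 had probes of opposite sign, 17 of them among the genes that passed.

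The ratio of each row was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, eBayes, two-sided, Benjamini-Hochberg at 5%). The pool counts as 1 control sample, so the test leaves out the spread among control mice, and with no dye swap a dye effect cannot be separated from an effect of nephritis. Counts of rows at 1 or more in size on every array were made without a test. The 27 gene lists were fixed before the data were examined; 26 had at least 5 measured genes and were tested with camera (preset inter-gene correlation 0.01) against all other named genes, two-sided, with Benjamini-Hochberg over the lists, and also with an estimated correlation, on ranks, and with fry. The sex-linked list, with 2 measured genes, was not tested; Xist and Kdm5d, at -0.12 ± 0.12 (SD, n = 3), are given as values. The median and mean of the platelet list (-0.01 and 0.23) and of the renin-angiotensin list (0.03 and -0.03) differ in sign, and camera ran with the mean in both.

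The genes named were chosen by a rule also fixed before: the 12 largest rises and falls among genes with a single symbol that passed and had the same sign on all arrays (clone and predicted names left aside), up to 3 passing members of each list with the largest size or, where none passed, the 2 with the smallest p, and a fixed set of inflammation, injury and nephron genes. Other genes named to spell out a count of 5 or fewer, and the falls outside runs, were chosen after their values were seen. A run is a set of probes with a mean of -1 or lower in which each has another such probe within 3 probe numbers.

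On simulated data for the 8605 rows with the observed spreads, the limma test recovered, on the base-2 scale, 58.2% of genes changed 1.5-fold. It recovered 77.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 3 false calls among 8405 unchanged rows. Only 200 rows were changed in this simulation, whereas 2405 passed in the data. The Benjamini-Hochberg cut depends on the share of changed rows, so these rates are not the power of the real test. No shared control pool and no dye effect was simulated there, so false calls that these would cause are not counted. Of 300 unshifted random lists of 25 genes, the camera step put 3% past an unadjusted threshold of 0.05, and it recovered all 20 lists shifted by 0.5, both with the preset and with an estimated correlation. Simulated genes varied independently of each other. In the run with shifted lists every list was shifted, and all genes of a list by the same amount. It therefore does not give the power for lists that change in part or beside unchanged lists. Alternatives fixed before were centring, scaling to equal spread, quantile normalization, each probe on its own, rows with values on 2 arrays, each array left out in turn, robust eBayes, a plain one-sample test, treat at 1.2-fold, false discovery rates of 10% and 1%, cut-offs of 1.5-fold and 3-fold, members whose probes disagree left out, and 2 other forms of camera. Leaving out rows with an exact 0, planned as an alternative, became the main setting. Alternatives chosen after seeing the data were zeros kept as values, in all rows or without rows at 0 throughout, runs left out, other log bases, and for the correlation between mice also each probe on its own and each array left out.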

Results

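Total RNA from the kidneys of BALB/c mice was profiled 3 days after injection of an antibody against the glomerular basement membrane (anti-GBM), a model of immune-mediated glomerulonephritis. Each of the 3 arrays compared the kidney of 1 nephritic mouse (mice 31, 32 and 33, here replicates 1, 2 and 3), labelled with Cy5, with a pool of kidney RNA from 5 normal BALB/c mice, labelled with Cy3. The deposited table holds 16281 probes and 1 log ratio per probe and array. The base of the logarithm and the direction of the ratio are not stated. Positive values are read here as higher in nephritic kidney. This is likely, because the labels give the nephritic kidney the red dye and red over green is the usual order; if it is wrong, every direction turns. Folds are given on a base-2 reading, the smallest that the common bases allow, and log ratios are on the deposited scale as mean ± SD over n = 3 mice. The number of arrays limits the precision.

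Among gene lists fixed beforehand, 16 of 19 measured tubular injury genes, 25 of 40 cell cycle genes and 12 of 27 chemokines and cytokines were higher at day 3 than in the control pool. Of 23 measured genes of the loop of Henle, distal tubule and collecting duct, 14 were lower. These 4 lists passed the set test camera, but not with an estimated correlation (adjusted p of 0.21 to 0.32). The calcium-binding protein S100a6 had the highest mean among named genes that passed, with a log ratio of 2.16 ± 0.21 (SD, n = 3), which is 4.48-fold on the base-2 reading. It was followed by the chemokine Ccl20 at 2.05 ± 0.14, the acute phase protein Saa2 at 1.90 ± 0.17 and the neutrophil chemoattractant Cxcl2 at 1.86 ± 0.12. The leukocyte adhesion molecule Vcam1 reached 1.80 ± 0.37 and Cxcl1 1.72 ± 0.15. The other rises among the top 12 were the lipid droplet protein Plin2 at 1.78, the TWEAK receptor Tnfrsf12a at 1.74, the metalloprotease Adam8 at 1.67, Lrr1 at 1.67, the kinetochore and spindle gene Knstrn at 1.66 and the AP-1 component Junb at 1.64. All 12 were higher on all 3 arrays, as the rule for naming them required (limma adjusted p of 0.000115 or lower, the highest for Vcam1).

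**Figure D1:**
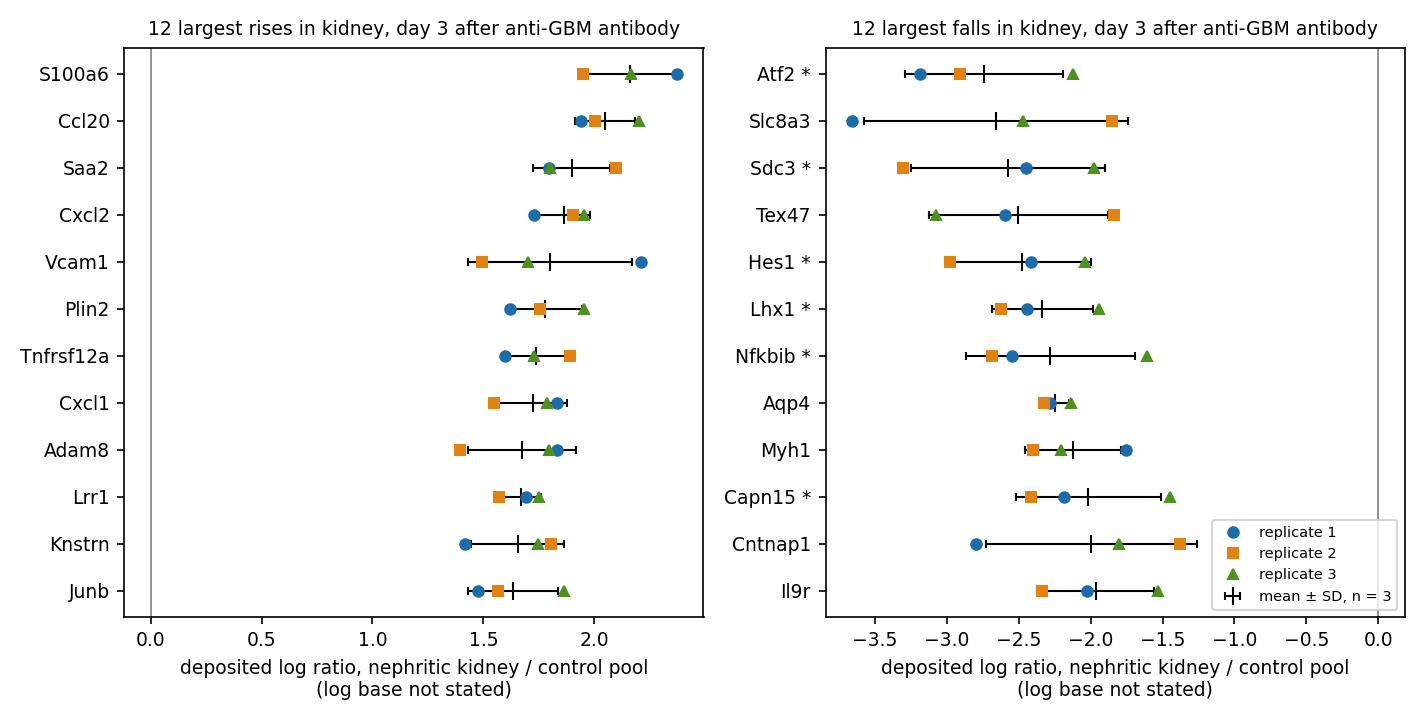
Deposited log ratio (x axis, base not stated) of the 12 largest rises (left) and the 12 largest falls (right) among named genes that passed the test; points are the 3 mice and bars the mean ± SD, n = 3. S100a6 leads the rises at a mean of 2.16, and an asterisk marks the 6 of 12 falls whose probe lies in a run of neighbouring low probes.

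Among the 12 largest falls, the water channel Aqp4 of the collecting duct had the smallest SD between mice, with a log ratio of -2.25 ± 0.10 (SD, n = 3), or 4.75-fold lower on the base-2 reading (limma adjusted p = 3.08e-05). The sodium/calcium exchanger Slc8a3 stood at -2.66 ± 0.92, Tex47 at -2.50 ± 0.62, the fast myosin heavy chain Myh1 at -2.12 ± 0.33, Cntnap1 at -1.99 ± 0.73 and the interleukin-9 receptor Il9r at -1.96 ± 0.40. The other 6 of the 12 largest falls were Atf2 at -2.74, Sdc3 at -2.58, Hes1 at -2.47, Lhx1 at -2.34, Nfkbib at -2.28 and Capn15 at -2.02. Each of these 6 was read by a probe lying in 1 of 5 runs of neighbouring low probes. Outside the runs, the next largest falls were the organic anion transporter Slco1a6 at -1.66 ± 0.25 and the stearoyl-CoA desaturase Scd1 at -1.64 ± 0.40. They were followed by the haemoglobin transcripts Hbb-b2 at -1.64 ± 0.26 and Hba-ps3 at -1.63 ± 0.30, Plb1 at -1.56 ± 0.53 and the bile acid conjugating enzyme Baat at -1.52 ± 0.16. This second ranking was added after the data were examined.

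Across all 8605 rows tested (7355 named genes and 1250 unnamed probes), 2405 (27.9%) passed the limma test at a 5% false discovery rate, 1241 higher and 1164 lower, and 3596 had an unadjusted p under 0.05. At least 1 on the deposited scale, 2-fold on the base-2 reading, was reached on every array by 55 rows upward and 37 downward, or 55 and 23 without rows in runs. The median of all means was 0.0075 and the median SD between mice 0.13. With 1 array left out, the count was 2440 without replicate 1, 1103 without replicate 2 and 1107 without replicate 3. It was 498 for a change beyond 1.2-fold and 6 with a plain one-sample test, which uses each row's own SD with 2 degrees of freedom. It was 1579 when exact zeros were kept as values in rows not at 0 throughout and 139 when they were kept everywhere.

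Genes of tubular injury rose together. Of the 19 measured, 16 rose, 1 fell (the trefoil peptide Tff3, at -0.45) and 2 did not pass. Adjusted over the list alone, 18 rose and 1 fell. Besides S100a6, the intermediate filament vimentin (Vim) stood at 1.58 ± 0.31, the keratin Krt20 at 1.55 ± 0.03 and Lcn2, the iron-carrier-binding protein NGAL, at 1.23 ± 0.26. The list's median was 0.98 (camera adjusted p = 1.32e-11; adjusted p = 0.21 with an estimated correlation). Cell cycle genes rose too (camera adjusted p = 5.32e-10; adjusted p = 0.21 with an estimated correlation): 25 of 40 rose and 1 fell, Ccnd1 at -0.33. Adjusted over the list alone, 25 rose and 2 fell. Mki67, a marker of dividing cells, stood at 1.37 ± 0.10, the mitotic kinase Cdk1 at 1.27 ± 0.13 and cyclin A2 (Ccna2) at 1.24 ± 0.07. Of 22 immediate early genes 14 rose and 3 fell, Dusp1 at -0.55, Gadd45g at -0.42 and Fosl1 at -0.27. Adjusted over the list alone, 15 rose and 3 fell. Junb was joined by Egr1 at 1.45 ± 0.32 and Myc at 1.33 ± 0.42 (camera adjusted p = 3.91e-05; adjusted p = 0.32 with an estimated correlation). Of the falls named here, Tff3 missed the threshold without replicate 2 (adjusted p = 0.051). Without replicate 2 and without replicate 3, Ccnd1 (adjusted p = 0.28 and 0.15), Gadd45g (0.095 and 0.066) and Fosl1 (0.25 and 0.14) did so.

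The inflammatory lists also moved upward. Chemokines and cytokines had 12 of 27 members higher and 2 lower, Il15 at -0.74 and Cxcl12 at -0.43. Adjusted over the list alone, 13 were higher and 2 lower (camera adjusted p = 0.00526; adjusted p = 0.32 with an estimated correlation). Cxcl12 missed the threshold without replicate 2 or 3 (adjusted p = 0.11 and 0.13). The monocyte chemoattractant Ccl2 stood at 1.12 ± 0.05 on 2 probes and the interferon-induced Cxcl10 at 0.49 ± 0.03. The small SD of Cxcl10 is that of an average of 2 probes that differed. In replicates 1, 2 and 3 they read 0.19, 0.29 and 0.32, and 0.85, 0.65 and 0.65. Il1b stood at 0.48 ± 0.24 and missed the threshold without replicate 3 (0.35, adjusted p = 0.067). Tnf did not pass at 0.02 ± 0.04 (adjusted p = 0.83), and its 3 probes disagreed in sign. For NF-kB signalling, 15 of 26 members rose and 2 fell, or 19 and 2 adjusted over the list alone (camera adjusted p = 0.00011; adjusted p = 0.27 with an estimated correlation). Beside Vcam1 the list held the IκB family member Bcl3 at 1.37 ± 0.22 and the inhibitor Nfkbia at 0.48 ± 0.06. Its 2 falls were the inhibitors Nfkbib, read by a probe in a run, and Nfkbie at -0.47. Acute phase and complement genes rose in 10 of 18 cases with no fall, and in 11 adjusted over the list alone, among them Saa3 at 1.15 ± 0.16 and complement C4b at 1.11 ± 0.24 (camera adjusted p = 0.000399; adjusted p = 0.27 with an estimated correlation). Antigen presentation genes rose in 10 of 14 cases, by both counts, with the class I genes H2-D1 at 0.64 ± 0.12 and H2-K1 at 0.54 ± 0.12. The 2 falls, by both counts, were the non-classical H2-T23 at -0.56 ± 0.19 and the class II transactivator Ciita at -0.28, lost without replicate 2 or 3 (adjusted p = 0.27 and 0.12). The list passed (camera adjusted p = 0.00593; adjusted p = 0.32 with an estimated correlation). The class II invariant chain Cd74 stood at 0.13 ± 0.01 and did not pass (adjusted p = 0.21).

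Matrix genes rose in 12 of 35 cases and fell in 3, Col5a2 at -0.51, Dcn at -0.48 and Thbs1 at -0.42. Adjusted over the list alone, 14 rose and 3 fell. The matricellular Ccn1 stood at 1.42 ± 0.22, the smooth muscle protein Tagln at 1.25 ± 0.40 and the protease inhibitor Timp1 at 1.01 ± 0.25. Fibronectin (Fn1) at 0.23 ± 0.25 and the basement membrane collagen Col4a1 at 0.24 ± 0.12 did not pass (adjusted p = 0.13 and 0.061). The list passed camera (adjusted p = 0.0309; adjusted p = 0.57 with an estimated correlation), but not without replicate 1 (adjusted p = 0.15). Without replicate 2 and without replicate 3, the calls of Col5a2 (adjusted p = 0.056 and 0.069), Dcn (0.076 and 0.11) and Thbs1 (0.068 and 0.11) were lost. Thbs1 was at -0.18 with values on at least 2 arrays (adjusted p = 0.23).

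Genes of the distal nephron fell in part. Of the 23 measured genes of the loop of Henle, distal tubule and collecting duct, 14 fell, none rose and 9 did not pass. One of the falls, the cotransporter Slc12a1 at -1.07, was read by a probe in a run. Adjusted over the list alone, 15 fell (median -0.41; camera adjusted p = 4.34e-06; adjusted p = 0.27 with an estimated correlation). After Aqp4 came parvalbumin (Pvalb), a calcium-binding protein of the distal convoluted tubule, at -1.52 ± 0.08, the chloride/bicarbonate exchanger Slc4a1, of acid-secreting cells and red cells, at -1.33 ± 0.27 and epidermal growth factor (Egf) at -1.08 ± 0.15. Members of the list that did not pass, named here after their values were seen, included the thiazide-sensitive cotransporter Slc12a3 at 0.10 ± 0.09, the sodium channel subunits Scnn1a, Scnn1b and Scnn1g at 0.06, 0.04 and 0.05, and the water channel Aqp2 at 0.01 ± 0.31. Erythroid genes fell in the same kidneys, in 4 of 9 cases. Proximal tubule genes moved both ways: 14 of 38 fell and 5 rose, and adjusted over the list alone 15 fell and 6 rose. The phosphate transporter Slc34a1 fell by 0.93 ± 0.33 and the organic cation and carnitine transporter Slc22a4 by 1.07 ± 0.08, whereas the vitamin D 24-hydroxylase Cyp24a1 rose by 1.54 ± 0.35. The list passed camera on the lower side (adjusted p = 0.0339; adjusted p = 0.32 with an estimated correlation), but not without replicate 1 (adjusted p = 0.14). Of 47 oxidative phosphorylation genes with a probe, only 14 had a value other than 0 on all arrays, so the counts cover a small part. Of these 14 genes 6 fell, or 7 adjusted over the list alone. By both counts 1 rose, Ndufa9 at 0.42, lost without replicate 3 (adjusted p = 0.071). The ATP synthase subunit Atp5k was at -0.57 ± 0.19. The list's call (camera adjusted p = 0.0429; adjusted p = 0.32 with an estimated correlation) was lost without replicate 1 or replicate 3 (adjusted p = 0.097 and 0.062). Umod and Kap were listed at 0 on most or all arrays and were not tested.

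Markers of cell types gave a mixed picture. Macrophage and myeloid genes rose in 12 of 27 cases, or 14 adjusted over the list alone, with the phagocyte oxidase subunit Ncf4 at 0.80 ± 0.05 and Cd68 at 0.53 ± 0.13. In the same list the macrophage growth factor receptor Csf1r fell by 1.32 ± 0.37, the resident macrophage antigen Adgre1 was at -0.35 and the scavenger receptor Cd163 at -0.71; these 3 fell by both counts. Cd163 was lost without replicate 3 (adjusted p = 0.064) and Adgre1 without replicate 2 or 3 (adjusted p = 0.087 and 0.064). The list passed camera upward (adjusted p = 0.036; adjusted p = 0.32 with an estimated correlation), but not without replicate 3 (adjusted p = 0.12) or with rows that had values on at least 2 arrays (adjusted p = 0.052). The neutrophil list did not pass (camera adjusted p = 0.28), with 6 of 16 genes higher and 1 lower, and 6 and 2 adjusted over the list alone. The calgranulin S100a9 was at 0.81, 0.90 and 1.80 in replicates 1, 2 and 3. B and plasma cell genes fell in 6 of 14 cases and rose in 1 by both counts. The rise, Blk at 0.31, was lost without replicate 2 or 3 (adjusted p = 0.086 and 0.11). Among the falls were immunoglobulin heavy chain Ighm at -0.59 ± 0.07 and the surrogate light chain gene Vpreb1 at -1.10 ± 0.16 (camera adjusted p = 0.0339; adjusted p = 0.32 with an estimated correlation). That list did not pass without replicate 1 (adjusted p = 0.098) or with camera on ranks (adjusted p = 0.061). Erythroid genes fell in 4 of 9 cases by both counts, Hbb-b2, Car1 with a probe in a run, the transcription factor Klf1 at -1.04 ± 0.38 and Hba-a1 at -0.67 (camera adjusted p = 0.00358; adjusted p = 0.32 with an estimated correlation). The list mean of -0.61 was -0.38 with exact zeros kept, where it did not pass (adjusted p = 0.15).

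Endothelial and mesangial genes fell in 5 of 20 cases and rose in 1, Edn1 at 0.40, by both counts. The falls included the endothelin receptor Ednrb at -0.74 ± 0.16 and Angpt2 at -0.78 ± 0.20. The list passed camera (adjusted p = 0.0356; adjusted p = 0.57 with an estimated correlation), but neither it nor Edn1 passed without replicate 3 (adjusted p = 0.20 and 0.13), and Edn1 was also lost without replicate 2 (adjusted p = 0.15). Podocyte genes split into 4 higher and 4 lower of 19, and 6 and 5 adjusted over the list alone (camera adjusted p = 0.69), with podoplanin (Pdpn) at 0.66 ± 0.17 and the membrane peptidase Mme at -0.57 ± 0.06. The slit diaphragm protein nephrin (Nphs1) stood at -0.39 ± 0.32 (adjusted p = 0.044) and was lost without replicate 1 (adjusted p = 0.058) or replicate 3 (adjusted p = 0.22). T and NK lymphocyte genes numbered 3 higher and 4 lower of 19 by both counts (camera adjusted p = 0.82). The platelet list, with 6 genes, did not pass (camera adjusted p = 0.44); its chemokine Pf4 rose by 1.35 ± 0.29.

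**Figure D2:**
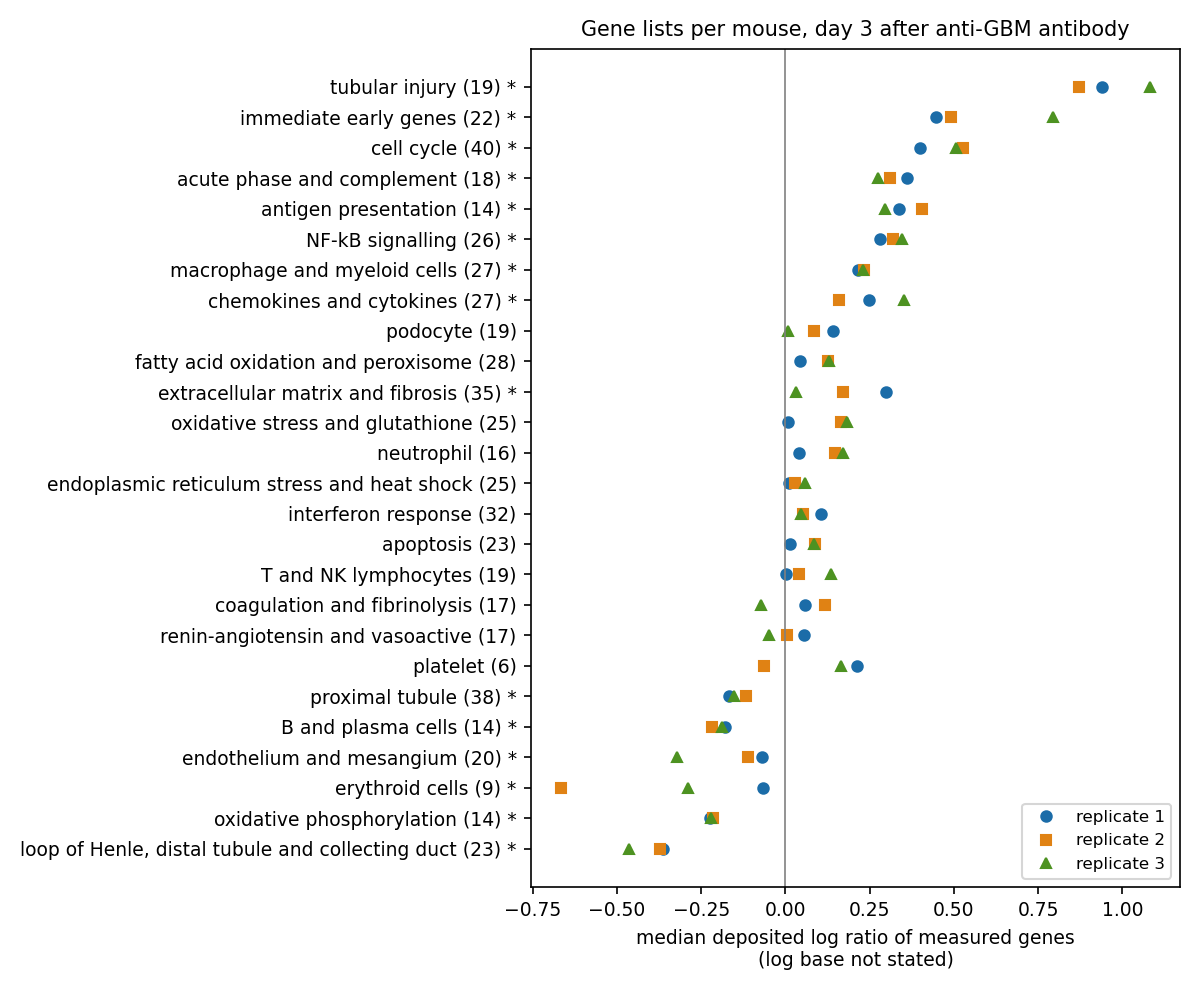
Median deposited log ratio (x axis, base not stated) of the measured genes of each of the 26 lists, 1 point per mouse, with the number of measured genes in brackets and an asterisk where the list passed camera. The median of gene means is highest for tubular injury, at 0.98; the loop of Henle, distal tubule and collecting duct list lies at -0.36, -0.37 and -0.47 in replicates 1, 2 and 3, and the erythroid list lies lower in replicate 2, at -0.67.

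In all, 15 of 26 lists passed camera with the preset correlation, 9 higher and 6 lower, and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. Estimated correlations were -0.0072 for tubular injury and -0.014 for cell cycle, below the preset 0.01, so a raised correlation did not cost these lists their call. With an estimated correlation camera uses the residual degrees of freedom, which are 2 with 3 arrays. With so few, an adjusted p above the threshold is not evidence against a list. For other passing lists the estimate lay above 0.01, such as 0.24 for matrix and 0.35 for endothelial and mesangial genes. Without replicate 1 12 lists passed with the preset correlation (9 higher, 3 lower), without replicate 2 15, and without replicate 3 12 (8 higher, 4 lower). With exact zeros kept in all rows 9 passed. The 6 lost were the matrix, endothelial and mesangial, macrophage and myeloid, B and plasma cell, erythroid and oxidative phosphorylation lists (adjusted p of 0.062 to 0.15). The self-contained test fry, which asks whether a list's own genes move one way on balance, called 18 lists, among them 13 of the 15, all but the matrix and the endothelial and mesangial lists (fry adjusted p = 0.11 and 0.16). The others it called were the neutrophil, coagulation, interferon response, endoplasmic reticulum stress and apoptosis lists (fry adjusted p of 0.011 to 0.027). Of the remaining lists, interferon response had 6 of 32 genes higher and 3 lower (6 and 3 adjusted over the list alone; camera adjusted p = 0.36), with the transcription factor Irf1 at 0.81 ± 0.09. Oxidative stress and glutathione genes were higher in 5 of 25 cases and lower in 2, or 7 and 2 over the list alone (camera adjusted p = 0.14, and 0.0497 without replicate 1), with haem oxygenase Hmox1 at 1.09 ± 0.22 and metallothionein Mt2 at 0.84 ± 0.09. Coagulation and fibrinolysis genes were higher in 5 of 17 and lower in 3, or 5 and 4 over the list alone (camera adjusted p = 0.69), with fibrinogen Fga at 1.00 ± 0.17 and tissue factor F3 at 0.73 ± 0.18. Fatty acid oxidation and peroxisome genes were higher in 8 of 28 and lower in 5, or 10 and 7 over the list alone (camera adjusted p = 0.44), with Pdk4 at 0.71 ± 0.17 and Pex3 at -0.68 ± 0.19. Endoplasmic reticulum stress and heat shock genes were higher in 6 of 25 and lower in 3, or 7 and 4 over the list alone (camera adjusted p = 0.44), with the small heat shock protein Hspb1 at 1.01 ± 0.05. Apoptosis genes were higher in 2 of 23 and lower in 1 by both counts (camera adjusted p = 0.49), and renin-angiotensin and vasoactive genes higher in 2 of 17 and lower in 3 by both counts (camera adjusted p = 0.64).

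Log ratios were correlated between the 3 mice. Across genes, which are not independent replicates, log ratios of replicates 2 and 3 correlated at Pearson's r = 0.81, replicates 1 and 2 at 0.75 and replicates 1 and 3 at 0.71, with Spearman's rho of 0.76, 0.64 and 0.61. Since all arrays share the control pool, unchanged simulated mice correlated at 0.14 to 0.16, and the covariance exceeded the simulated one by 0.111, 0.0905 and 0.0879. The same sign on all 3 arrays was seen in 61.1% of rows, and in 32.6% of rows of the unchanged simulated mice. Control mice were simulated with the spread seen among the nephritic mice, since their own is not in the data. A larger spread among them would raise the simulated correlation and share. The simulated mice shared only the sampling error of the pool, with no dye or probe effect common to all arrays. Such an effect would also raise the observed values, so the excess cannot be put down to nephritis alone. Xist stood apart: it was at -0.17 and -0.10 in replicates 1 and 2 and at -3.18 in replicate 3, and did not pass (-1.15 ± 1.76, adjusted p = 0.13).

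**Figure D3:**
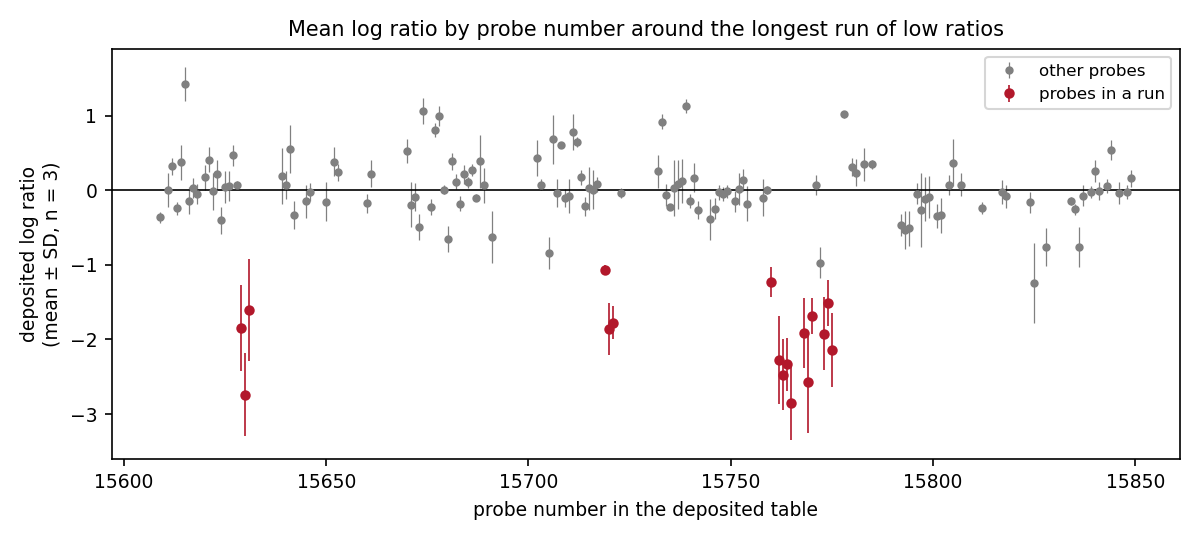
Mean deposited log ratio ± SD (y axis, base not stated, n = 3) of probes measured on all arrays, by probe number in the deposited table, around the longest run of 11 low probes; probes in runs are red. The 24 probes in all 5 runs had a median of -1.81.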

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

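Tests with zeros kept, runs left out, other log bases, and those on the correlation between mice were chosen after the data were examined. The count of 2405 rows changed stayed within 1.5 times under centring, scaling, quantile normalization, single probes, values on 2 arrays, robust eBayes, runs left out and a 10% rate. It ranged from 1103 to 2440 with 1 array left out, where 1994, 1085 and 1078 of the 2405 calls were kept without replicate 1, 2 and 3 and none changed sign. It was 1056 at 1%, 498 with treat and 6 with a plain one-sample test, which has 2 degrees of freedom and gave 2232 rows an unadjusted p under 0.05. With zeros kept it was 139, with a prior of 0.441 degrees of freedom in place of 5.9. Part of that drop goes with 2539 rows that then have no spread. Without these rows, at 0 throughout, the prior was 3.57 and the count 1579. The count of 92 rows at 2-fold was 78 without runs (55 higher, 23 lower) and became 304 at 1.5-fold, 16 at 3-fold, and 226 or 1056 if the scale is a natural or base-10 logarithm. Asked of the 2 arrays kept, it was 129 without replicate 1 (69 higher, 60 lower), 99 without replicate 2 and 109 without replicate 3. Of lists, 15 passed, 9 with zeros kept, 14 with zeros kept without rows at 0 throughout (the endothelial and mesangial list was lost, adjusted p = 0.054), 14 with values on 2 arrays (macrophage list lost) and 0 with an estimated correlation in camera (4 at an unadjusted p under 0.05; 14 on ranks, all but B and plasma cells at an adjusted p of 0.061). With 1 array left out, 12, 15 and 12 lists passed without replicate 1, 2 and 3. Mean r between mice was 0.756, 0.680 with zeros kept in both ways, and 0.713 to 0.809 with 1 array left out. For lists and r the cause was not tested. Of 102 named genes that passed, 15 lost the call without 1 of the arrays, 26 with treat, 102 with the plain test, 90 with zeros kept and 11 with zeros kept without rows at 0 throughout. Among all called rows, the sign turned in 4 without runs (2 of them called both ways), 6 with values on 2 arrays and 8 with zeros kept in either way. Among named genes and lists, directions turned in 2, neither past the threshold: the T and NK lymphocyte list (mean 0.0157 with values on 2 arrays, where camera turned, -0.00403 and -0.00298 with zeros kept, -0.00397 to 0.0379 with 1 array left out) and Tnf (-0.00219 and -0.107 on 2 of its probes); the cause was not tested. Signal over background was not part of the table, so what dim probes limit is unknown.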

Other observations

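The tests of probe position and dye on the runs, of genes in runs with no second probe, and of a faulty Xist spot were chosen after the result was seen; the others were written before.

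Replicate 3 differed from the other mice in several genes beyond Xist, chosen here after their values were seen and not tested, since it is 1 mouse. The other replicates were not searched in this way. Across all genes replicate 1 was the least alike, at r = 0.75 and 0.71 with replicates 2 and 3, against 0.81 between those. Lower in replicate 3 were the fibrillar collagen Col3a1, at 1.43, 1.00 and 0.22 in replicates 1, 2 and 3, and the endothelial co-receptor endoglin (Eng), at 0.18, -0.07 and -0.87. Higher in replicate 3 were S100a9 at 0.81, 0.90 and 1.80 and the myeloid gene Slfn4 at -0.12, 0.03 and 0.95. The B-cell chemoattractant Cxcl13 was at 1.26, 1.29 and 0.44.

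Low ratios clustered by probe number: of 86 probes with a mean of -1 or lower, 24 had another within 3 probe numbers, more than in any of 10000 random placements (median 2, highest 20), whereas of 95 probes at 1 or higher 8 did, a number that 806 placements reached. For the 7 of 22 named genes in runs with a second measured probe elsewhere, among them Akt2, Plod2 and Kcnj12, the median of those probes was 0.036 with a standard error of 0.12, and 0 of 7 was at -0.5 or lower, which argues against a fall of those transcripts as the source. For the other 15 genes, among them Hes1, Lhx1 and Nfkbib, a true fall stays open. A position effect on the array is a candidate explanation if probe numbers follow the layout, which the sources do not state. With 0 dye-swapped arrays, excess Cy3 fluorescence was not tested, and for those 15 genes it cannot be told apart from a lower transcript level.

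Xist, the non-coding RNA that silences an X chromosome in female cells, was low in replicate 3 on both of its probes, at -3.38 and -2.98, against -0.32 to -0.03 in the other mice. The smaller of the 2 differences was -2.95, so 1 faulty spot is argued against. A male in replicate 3 set against a mostly female pool may account for it. The prediction was clearly higher Y-linked genes, and male-biased genes above female-biased ones, in replicate 3. Neither was seen, as the Y-linked Kdm5d differed by only 0.055. All 5 male-biased genes were lower in replicate 3 than in the others, with differences of -0.01 to -0.23. Of the 2 female-biased genes, Abcc3 differed by -0.10 and Cyp2a5 by 0.17. With 1 Y-linked gene and 7 others measured, these values do not decide. Genes with higher expression in male kidney minus those with higher expression in female kidney differed between replicate 3 and the others by -0.095, within 1 SD (0.099) of the 21 ways to divide the 7 measured genes; the Y-linked Kdm5d was at -0.03, -0.26 and -0.09, and Uty and Eif2s3y were listed at 0 on most arrays. The labels do not give the sex of the mice.

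The 3 arrays allow 4 sign patterns, too few for a share under 0.05. The real one gave 2405 rows, 1 of 4 patterns with as many, and the highest of the other patterns gave 0. Turning 1 array cancels any signal that the arrays share, from nephritis, the common pool or the dye. The contrast therefore says nothing about the source of that signal.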
